A study of Mus musculus with 32 samples.

How the data were processed

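Per the labels' protocols, the samples are primary hippocampal neurons of newborn mice, treated at DIV16, with RNA taken up in Trizol and extracted with chloroform. The labels give TruSeq Stranded Total RNA as the library kit for the total RNA samples and carry the same text for the miRNA samples. The kit used for small RNA is therefore not given in the sources used here. Per the submitters' processing notes, reads were quantified with Salmon against GRCm38 and compared with DESeq, and the versions of these tools are not given in the sources used here. There were 32 samples, 16 per assay, with 4 DMSO, 6 DHPG and 6 forskolin (FSK) libraries in each.

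The deposited count tables hold 51267 features for total RNA and 1963 for miRNA. Their values are estimated counts from Salmon per the submitters' processing notes, and 26.6% of the deposited total RNA values and 3.68% of the deposited miRNA values are not whole numbers. These estimated counts, as deposited, were rounded to whole numbers before every test. The deposited tables name their control columns differently from the samples. These columns were matched to the DMSO samples by number, and log2 fold changes recomputed with that match correlated with those of the authors' deposited tables at 0.9995 or higher. The authors' tables give a log2 fold change, its standard error, a p-value and an adjusted p-value, and those values are quoted only where the authors' deposited table is named. Among the total RNA features 24 names look like dates, the mark of a spreadsheet conversion. They carry 0.209% of the counts and were kept under the names they have.

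Each comparison was tested with the edgeR quasi-likelihood F test with robust estimation, on counts scaled by trimmed mean of M values (TMM) factors. Features were filtered by filterByExpr with a minimum count of 10, leaving 17173 for total RNA and 556 for miRNA. The 3 groups of an assay shared 1 fit without a replicate block, and p-values were adjusted by the Benjamini-Hochberg method with a limit of 0.05. Adjusted p without a tool named comes from this edgeR fit. P-values of single features measure the spread between libraries, while those of gene lists and of the Mantel test, described below, have other bases. The labels do not state whether the replicates are separate cultures or separate animals. Levels are counts scaled to library size and TMM factor (CPM), given as mean ± SD over libraries, and log2 fold changes are given ± their standard error. The prior count for log2 CPM was 2.

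Gene lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. This test sets a list against the other genes, and at the preset correlation its p rests on the spread between genes. Camera with an estimated correlation was run beside it, and so was fry, which tests a list against no change and not against the other genes. Members of a list were counted both with p adjusted over all genes tested and with p adjusted over the list alone. For total RNA the lists were immediate-early transcription factors, immediate-early effectors, CREB/CRTC and cAMP-responsive genes, late-response and secreted synaptic genes, MAPK negative feedback, cAMP and PKA pathway components, the group I mGluR pathway, glutamate receptors and postsynaptic density, and lncRNA and host transcripts. Further lists were ribosomal proteins, mitochondrially encoded mRNAs, replication-dependent histones, and heat shock and unfolded protein response. Cell lists held markers of excitatory neurons, inhibitory neurons, astrocytes, microglia, the oligodendrocyte lineage, endothelium, fibroblast, mural and meningeal cells, cycling cells, and choroid plexus and ependyma. For miRNA the lists were activity-regulated, Dlk1-Dio3 cluster, neuron-enriched, microglia and blood, oligodendrocyte lineage, endothelial, mural and fibroblast, muscle and let-7. All lists were fixed before the data were examined.

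The named genes follow a rule fixed at the same time. For each total RNA comparison with DMSO these are the 10 largest positive and 10 largest negative log2 fold changes among features that pass and have an average log2 CPM of at least 0. For FSK against DHPG they are the 5 largest in each direction. Each list adds up to 4 passing members of smallest p, or the 2 of smallest p as values where none passes. Up to 5 passing lncRNAs and up to 8 passing miRNAs of smallest p are named, or 3 miRNAs as values where none passes. A fixed group is given whatever its result: Fos, Arc, Egr1, Npas4, Nr4a1, Sik1, Crem, Per1, Bdnf, Homer1, Grm5, Arl5b, miR-132-3p, miR-212-3p and miR-124-3p. Trh, whose average log2 CPM is under 0, C1qa, C1qc, Snhg14 and Snhg15 were named outside this rule after their values were seen. Some genes that the rule selects are not reported here.

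Alternatives fixed in advance were DESeq2 size factors, library totals without TMM, the DESeq2 Wald test, limma-voom with sample quality weights, no filter, a filter of 50 counts in 4 libraries, and the 2 groups compared alone. A replicate block, 1 surrogate variable from svaseq, a minimum fold of 1.2 and leaving out each library in turn were others. Alternatives chosen after the data were seen were a term for the library set, each library set alone, FSK 4 and FSK 5 left out, and removal of mitochondrial rRNA, 7SL and 7SK. Library sets were defined by the data, with more than 5% mitochondrial rRNA in the deep set, which holds at least 38409918 counts per library against at most 24892959 in the shallow set. Libraries with the same replicate number were taken as paired only if their residuals correlated above 0.1, and no pairing enters the values reported.

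The log2 fold changes of the 2 treatments share the 4 DMSO libraries, so their correlation was set beside 20 simulated data sets of unchanged groups and beside the 6 ways of splitting the controls 2 and 2. Group labels were rearranged up to 100 times per comparison, freely and within library sets. Random sets of genes matched in 20 expression bins were drawn 10000 times, and the Mantel test used 100000 permutations. Where a group has few counts the fold is given with a 95% interval, or as a bound with a floor of 3 counts, and these cover counting error only.

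The pipeline was tested on simulated counts with the group sizes, depths and library sets of the data. Genes were drawn independently, once per comparison, so variation that genes share between libraries is lacking. False calls that such variation would bring are not counted here. For FSK against DMSO, edgeR recovered 13 of 67 genes changed 1.5-fold, 38 of 67 changed 2-fold and 55 of 66 changed 4-fold, with 0 false calls among 106. For DHPG against DMSO the numbers were 8 of 67, 32 of 67 and 55 of 66, with 10 false calls among 105. For FSK against DHPG they were 13 of 67, 36 of 67 and 52 of 66, with 3 false calls. For miRNA, FSK against DMSO, they were 4 of 20, 12 of 20 and 17 of 20, with 0 false calls. Absence of a call therefore says little about changes of 1.5-fold.

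Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, sva 3.50.0, Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9. Gene positions are from the RefSeq annotation of GRCm38.p6. No sequence-based check was made.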

Results

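Total RNA and miRNA were profiled in cultured hippocampal neurons of newborn mice at 16 days in vitro. Cultures received one of 3 treatments for 30 minutes: 50 µM forskolin (FSK), which activates adenylyl cyclase and so raises cAMP, 30 µM DHPG, an agonist of the group I metabotropic glutamate receptors, or DMSO. Each assay held 4 DMSO, 6 DHPG and 6 FSK libraries. Total RNA libraries held 20677117 to 59958600 counts and miRNA libraries 1748819 to 6756996.

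The total RNA libraries fell into 2 sets by depth and by mitochondrial rRNA, a difference the labels do not describe. DMSO 2 to 4, DHPG 6 and FSK 4 to 6 held 38409918 to 59958600 counts with 10.8 to 27.7% mitochondrial rRNA (the deep set). DMSO 1, DHPG 1 to 5 and FSK 1 to 3 held 20677117 to 24892959 with 1.47 to 2.92% (the shallow set). Treatment and library set are therefore partly confounded, most of all for DHPG against DMSO, where the deep set has 1 DHPG library and the shallow set 1 DMSO library. FSK 4 and FSK 5 lay farthest out on the first principal component, which carried 44.1% of the variance in total RNA and 51.0% in miRNA. Values with a term for the library set, and values without FSK 4 and FSK 5, are given beside the main ones.

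**Figure D1:**
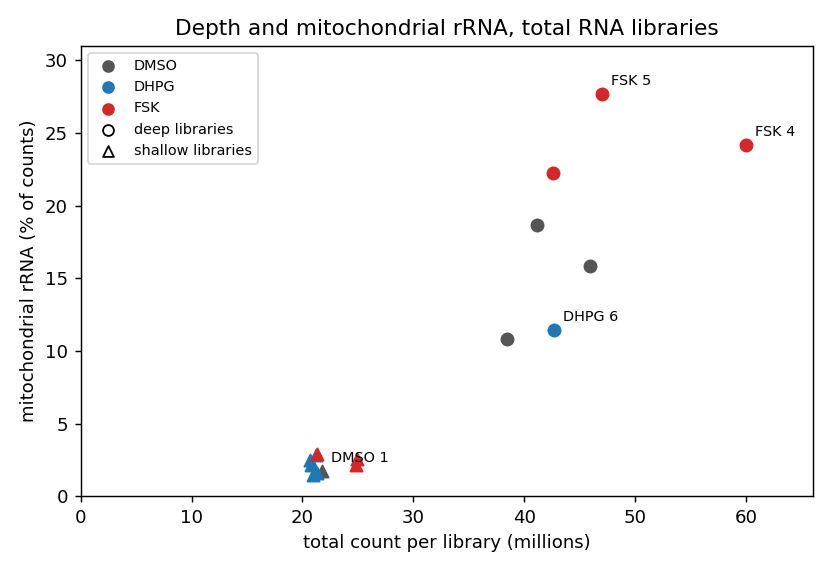
Total count of each of the 16 total RNA libraries (x axis) against the percentage of its counts in mitochondrial rRNA (y axis), coloured by treatment. Shallow libraries hold 1.47 to 2.92% and deep libraries 10.8 to 27.7%.

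Forskolin raised immediate-early genes, which neurons transcribe within minutes of stimulation. Fosb, a subunit of the AP-1 transcription factor, went from 5.34 ± 3.995 CPM in DMSO (n = 4) to 85.8 ± 7.22 CPM in FSK (n = 6), a log2 fold change of 3.996 ± 0.45 (adjusted p = 0.00067). Klf4, a zinc-finger transcription factor, went from 1.36 ± 0.70 to 25.5 ± 20.4 CPM (4.21 ± 0.64, adjusted p = 0.0080). Fos rose from 93.0 ± 57.0 to 544 ± 170 CPM (2.55 ± 0.45, adjusted p = 0.021), and Arc, which drives endocytosis of AMPA receptors, from 43.6 ± 25.4 to 198 ± 41.6 CPM (2.18 ± 0.31, adjusted p = 0.0070). Each of these 4 genes was above every DMSO library in 6 of 6 FSK libraries. The transcript 1700016P03Rik, host of the activity-regulated miR-212 and miR-132, rose from 0.98 ± 0.59 to 12.6 ± 2.07 CPM (3.66 ± 0.44, adjusted p = 0.0016), likewise in 6 of 6.

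The remaining largest increases include regulators of transcription and signalling. Maff, a small Maf transcription factor, rose by 3.52 ± 0.51 log2 units (adjusted p = 0.0072), Btg2, an antiproliferative immediate-early gene, by 2.42 ± 0.38 (adjusted p = 0.010) and the small GTPase gene Arl4d by 2.66 ± 0.23 (adjusted p = 4.5e-05; 4.52 ± 0.90 to 28.6 ± 3.19 CPM). Rasd1, a Ras-related G protein induced by dexamethasone, rose by 2.67 ± 0.60 (adjusted p = 0.049), and the unannotated Gm17971 and Gm38257 by 2.78 ± 0.42 (adjusted p = 0.0072) and 2.62 ± 0.49 (adjusted p = 0.025). All 6 were above every DMSO library in 6 of 6 FSK libraries. Nuclear receptor genes Nr4a1 (2.36 ± 0.41, adjusted p = 0.017) and Nr4a2 (2.40 ± 0.33, adjusted p = 0.0051), both CREB targets, rose, as did Ptgs2, the inducible cyclooxygenase (1.93 ± 0.28, adjusted p = 0.0072), and Egr2 (1.81 ± 0.27, adjusted p = 0.0072). Rgs2, which limits signalling by Gq, rose by 1.39 ± 0.12 (adjusted p = 4.5e-05) and Sik1, a kinase that restrains CREB coactivators, by 1.32 ± 0.25 (adjusted p = 0.025). These 6 also exceeded every DMSO library in 6 of 6. The thyrotropin-releasing hormone gene Trh had 144 counts in FSK and 2 in DMSO, a ratio of 47.0 (95% interval 12.8 to 392; log2 fold change 5.19 ± 0.65, adjusted p = 0.0019).

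**Figure D2:**
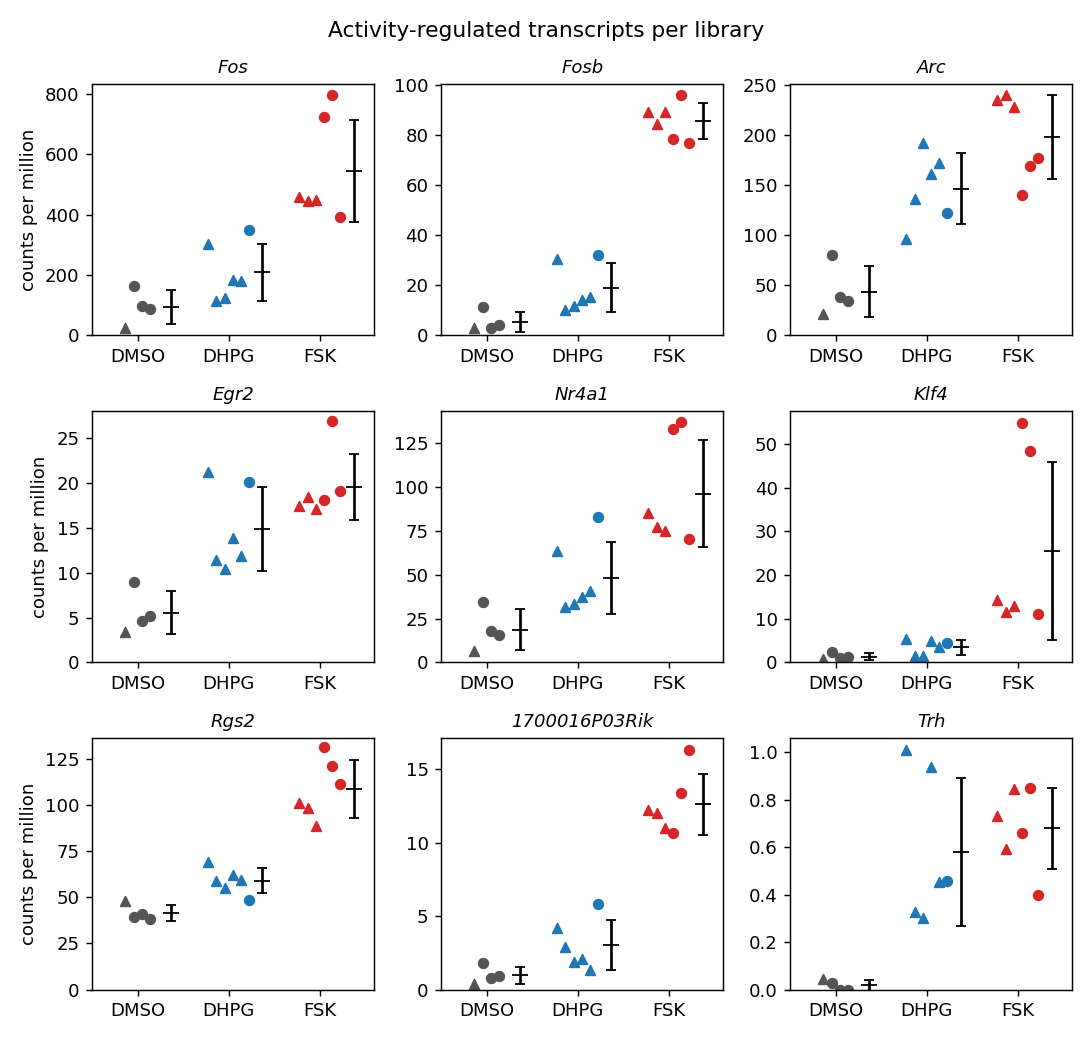
Level of 9 activity-related genes in each total RNA library (CPM, y axis) by treatment (x axis), with mean ± SD; triangles are shallow and circles deep libraries. Fosb averages 5.34, 19.0 and 85.8 CPM in DMSO, DHPG and FSK.

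With forskolin Pcsk1n, which encodes the convertase inhibitor proSAAS, fell from 127 ± 34.4 to 30.4 ± 19.5 CPM (-2.07 ± 0.45, adjusted p = 0.047), and the forkhead factor gene Foxo6 from 23.5 ± 5.23 to 8.87 ± 1.54 CPM (-1.41 ± 0.21, adjusted p = 0.0072). Shank3, a scaffold of the postsynaptic density, was lower too, from 133 ± 7.79 to 77.3 ± 9.94 CPM (-0.78 ± 0.12, adjusted p = 0.010), and Grin1, the obligatory NMDA receptor subunit, from 251 ± 22.9 to 162 ± 20.01 CPM (-0.64 ± 0.14, adjusted p = 0.050). Dagla, which makes the endocannabinoid 2-AG, fell by 0.67 ± 0.13 log2 units (adjusted p = 0.034) and Rtn4rl2, a receptor of the Nogo family, by 1.01 ± 0.19 (adjusted p = 0.030). Zinc-finger genes Zfp771 (-1.18 ± 0.26, adjusted p = 0.045) and Zfp579 (-0.90 ± 0.18, adjusted p = 0.034), the Myc relative Bmyc (-1.14 ± 0.23, adjusted p = 0.034), Kazald1 (-0.94 ± 0.20, adjusted p = 0.044) and the kinase gene Lmtk3 (-0.91 ± 0.20, adjusted p = 0.047) fell as well. The lncRNAs AW047730 (-1.20 ± 0.24, adjusted p = 0.035) and 2900079G21Rik (-1.16 ± 0.21, adjusted p = 0.021) also fell. The 10 largest decreases lay below every DMSO library in 6 of 6 FSK libraries. Excitatory neuron markers were also lower by 0.82, 0.67 and 0.39 in mean log2 CPM in FSK 4, 5 and 6 than in the 3 deep DMSO libraries, and differed by -0.02 to 0.01 from DMSO 1 in FSK 1 to 3.

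In all, 60 features were higher and 79 lower with FSK at adjusted p under 0.05, and 3658 had unadjusted p under 0.05. The median size of the 139 changes was 0.79 log2 units. With the library-set term 593 were higher and 1029 lower, including all 139. Without FSK 4 and FSK 5 and with that term 56 passed, of which 35 were shared. Of the 10 largest increases all but Rasd1 (2.27, adjusted p = 0.059) passed there, and of the 10 largest decreases only AW047730 did (-1.41, adjusted p = 0.039). Pcsk1n differed between sets, at -3.29 in the deep and -0.96 in the shallow libraries. Leaving out 1 library moved the count of 139 by more than 1.5-fold for DMSO 1 (60), DMSO 2 (31), DMSO 3 (12), DMSO 4 (47), DHPG 1 (224), DHPG 2 (47), DHPG 5 (61), DHPG 6 (427), FSK 1 (77), FSK 2 (68), FSK 4 (47) and FSK 5 (35).

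Some well-known activity genes did not pass with FSK. Npas4, a neuron-specific activity-dependent factor, had 126 ± 14.2 CPM against 35.7 ± 37.9 in DMSO (1.82 ± 0.52, adjusted p = 0.088), above every DMSO library in 6 of 6, and passed with the library-set term (2.21, adjusted p = 0.026). Crem, a cAMP-responsive modulator of transcription, had 0.53 ± 0.16 (adjusted p = 0.096; 0.048 with the term). Values were 0.44 ± 0.48 for Egr1 (adjusted p = 0.63; 0.89 with the term, adjusted p = 0.018), 0.37 ± 0.15 for Homer1 (adjusted p = 0.18), 0.14 ± 0.24 for the clock gene Per1 (adjusted p = 0.78) and 0.14 ± 0.16 for the neurotrophin gene Bdnf (adjusted p = 0.67). The receptor gene Grm5 (0.12 ± 0.17, adjusted p = 0.73) and the small GTPase gene Arl5b (0.27 ± 0.20, adjusted p = 0.46) did not pass either.

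Among gene lists, 8 of 30 measured immediate-early transcription factors passed with FSK, all higher. Adjusted over the list alone 17 were higher and 2 lower (median 0.66, camera adjusted p = 3.5e-10; adjusted p = 0.31 with an estimated correlation). Of 31 immediate-early effectors 8 were higher, 13 over the list alone (median 0.58, camera adjusted p = 5.5e-10; adjusted p = 0.26 with an estimated correlation). Fry, which tests a list against no change rather than against the other genes, gave adjusted p of 0.0093 and 0.0036 for these lists. Of 36 CREB/CRTC and cAMP-responsive genes 6 were higher, with 11 higher and 2 lower over the list alone (median 0.14, camera adjusted p = 0.00075; adjusted p = 0.35 with an estimated correlation). In mean log2 CPM the immediate-early transcription factors stood 0.48 to 1.33 and the effectors 0.55 to 1.09 above the mean of the 3 deep DMSO libraries in FSK 4 to 6. In FSK 1 to 3 they stood 1.48 to 1.64 and 0.86 to 0.91 above DMSO 1, the lone shallow DMSO library. Oligodendrocyte lineage markers, lowest in DMSO 1 among the DMSO libraries, shifted further in FSK 1 to 3, by 2.30, 1.80 and 2.06. In FSK 4, 5 and 6 they shifted by 1.19, 1.48 and -0.52 from the deep DMSO libraries. The shift was not particular to FSK: DHPG 1, also shallow, stood 1.90 above DMSO 1, and DHPG 2 to 5 differed by -0.06 to 0.57.

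**Figure D3:**
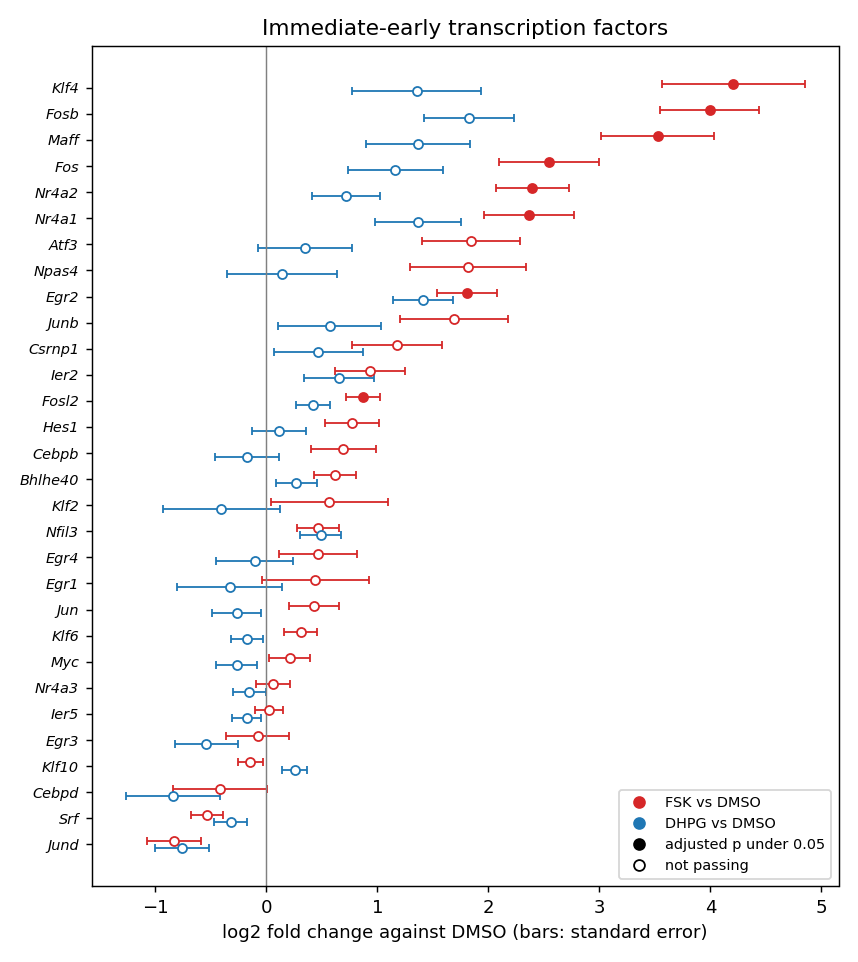
Log2 fold change ± SE (x axis) of 30 immediate-early transcription factor genes (y axis) for FSK against DMSO (red) and DHPG against DMSO (blue), filled where adjusted p is under 0.05. Fosb has 3.996 with FSK and 1.82 with DHPG.

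Of 45 lncRNA and host transcripts 4 were higher with FSK, 10 over the list alone (median 0.33, camera adjusted p = 0.0011; adjusted p = 0.26 with an estimated correlation). They include the snoRNA hosts Gas5 (0.75 ± 0.15, adjusted p = 0.033) and Snhg1 (0.67 ± 0.11, adjusted p = 0.014), each above every DMSO library in 6 of 6. C130071C03Rik, the host of a miR-9 gene, rose by 0.55 ± 0.12 (adjusted p = 0.045; 5 of 6). Among all 1560 annotated lncRNAs tested, 9 were higher and 2 lower.

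Other lists lay lower with FSK. Of 36 glutamate receptor and postsynaptic density genes 1 was lower, 6 over the list alone (median -0.14, camera adjusted p = 0.0062; adjusted p = 0.70 with an estimated correlation). Of 28 replication-dependent histones 0 passed and 1 was lower over the list alone (median -0.54, camera adjusted p = 6.3e-05; adjusted p = 0.70 with an estimated correlation), led by Hist1h2ad (-1.57 ± 0.39, adjusted p = 0.065) and Hist1h3c (-1.32 ± 0.49, adjusted p = 0.15). The 13 excitatory neuron markers had a median of -0.41, with 5 lower over the list alone (camera adjusted p = 0.0012; adjusted p = 0.26 with an estimated correlation). Their smallest p belonged to Neurod2 (-0.64 ± 0.18, adjusted p = 0.086) and Slc17a7 (-0.57 ± 0.15, adjusted p = 0.080), and without FSK 4 and FSK 5 the list's median was -0.39, or -0.15 with the library-set term added.

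Markers of microglia, the resident macrophages of the brain, had a median of 2.98 with FSK. All of the 14 missed the limit over all genes tested, while 13 were higher over the list alone (camera adjusted p = 2.9e-05; adjusted p = 0.63 with an estimated correlation). The lysosomal protease gene Ctss had 4.23 ± 1.15 (adjusted p = 0.081) and the chemokine receptor gene Cx3cr1 3.57 ± 0.99 (adjusted p = 0.083). Without FSK 4 and FSK 5 the list's median was 0.84, and with the library-set term added it was 0.00, with Ctss at 0.51 and Cx3cr1 at 0.78. Cycling cell markers had a median of 0.70 (12 measured, 1 higher over the list alone; camera adjusted p = 0.0017; adjusted p = 0.70 with an estimated correlation) and without these libraries 0.64, or 0.05 with the term added. Top2a had 1.02 ± 0.30 (adjusted p = 0.091) and Ccna2 0.87 ± 0.33 (adjusted p = 0.15).

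The other lists gave no camera call with FSK. Camera adjusted p was 0.46 for late-response and secreted synaptic genes (1 higher), 0.11 for MAPK negative feedback (1 higher), 0.28 for cAMP and PKA pathway components (0 passed) and 0.58 for the group I mGluR pathway (1 higher, 2 lower; median 0.01 and mean 0.03, but camera direction down). It was 0.76 for ribosomal proteins, 0.12 for mitochondrially encoded mRNAs, 0.88 for heat shock and unfolded protein response (median 0.06, mean -0.01, direction up), 0.070 for inhibitory neurons and 0.75 for astrocytes (median -0.07, mean 0.01, direction down). It was 0.070 for the oligodendrocyte lineage (4 higher and 1 lower over the list alone), 0.75 for endothelium (5 of 10 measured; median -0.22, mean 0.19, direction up), 0.28 for fibroblast, mural and meningeal cells, and 0.15 for choroid plexus and ependyma. Members of smallest p, none passing, were Crtc1 (-0.59) and Pde7a (0.40) for cAMP components, Rpl10 (0.44) and Rpsa (-0.44) for ribosomal proteins, mt-Co3 (1.53) and mt-Cytb (0.57), Dnajb1 (0.32) and Hspa1b (-0.89) for heat shock. For cell types they were Dlx2 (-0.79) and Sst (-1.12), Aqp4 (1.01) and Fgfr3 (-0.31), Olig1 (-0.78), Pecam1 (0.77) and Slco1a4 (1.23), Pdgfrb (-0.36) and Rgs5 (0.75), and Ccdc153 (1.18) and Kl (-0.52).

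With DHPG, 1 feature passed. Trh, whose peptide product releases thyrotropin and also acts as a neuromodulator, had 86 counts in DHPG against 2 in DMSO, a ratio of 40.5 (95% interval 10.9 to 340; log2 fold change 4.97 ± 0.66, adjusted p = 0.018), and was above every DMSO library in 6 of 6 DHPG libraries. Several immediate-early genes, though not Egr1 or Npas4, were at least 2-fold higher on average without passing. Arc had 147 ± 35.1 CPM against 43.6 ± 25.4 in DMSO (1.75 ± 0.31, adjusted p = 0.26) and Egr2, a zinc-finger transcription factor, 14.8 ± 4.68 against 5.55 ± 2.41 (1.41 ± 0.27, adjusted p = 0.33), each above every DMSO library in 6 of 6. Values were 1.82 ± 0.40 for Fosb (adjusted p = 0.40, 5 of 6), 1.61 ± 0.41 for 1700016P03Rik (5 of 6), 1.37 ± 0.39 for Nr4a1 (4 of 6) and 1.16 ± 0.43 for Fos (4 of 6). In the authors' deposited table Egr2 (1.42, adjusted p = 0.0013), Fosb (1.83, adjusted p = 0.0097), Arc (1.51, adjusted p = 0.027) and Nr4a1 (1.37, adjusted p = 0.036) pass and Fos (1.17, adjusted p = 0.11) does not.

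The count with DHPG depends on the fit. In edgeR 2129 features had unadjusted p under 0.05 and 1 passed, against 9 with DESeq2 (7 higher, 2 lower) and 5940 with limma-voom. With the library-set term edgeR called 0, with 400 at unadjusted p under 0.05 (39 with DESeq2), and Trh then had 4.77 with adjusted p = 0.052, as did Egr2 with 1.71. Leaving out DMSO 1 (2), DMSO 2 (5), DMSO 3 (0) or DMSO 4 (0) moved the count. Other genes named in advance were Sik1 (0.36 ± 0.24, adjusted p = 0.46), Npas4 (0.14 ± 0.49, adjusted p = 0.90), Crem (0.08 ± 0.16, adjusted p = 0.80), Egr1 (-0.33 ± 0.47, adjusted p = 0.73), Per1 (-0.17, adjusted p = 0.72), Bdnf (-0.14, adjusted p = 0.68), Homer1 (-0.12, adjusted p = 0.69), Grm5 (-0.22, adjusted p = 0.51) and Arl5b (-0.23, adjusted p = 0.55).

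No member of any list passed over all genes tested with DHPG. The immediate-early transcription factors had a median of 0.20 with 3 higher and 1 lower over the list alone (camera adjusted p = 0.022; adjusted p = 0.70 with an estimated correlation), and with the library-set term 13 were higher over the list alone (median 0.54). The effectors had 0.18 with 4 higher over the list alone (camera adjusted p = 0.033; adjusted p = 0.70 with an estimated correlation), and with both the term and an estimated correlation p was 0.0035. In mean log2 CPM the immediate-early transcription factors stood 0.55 to 1.18 and the effectors 0.37 to 0.60 above DMSO 1, the lone shallow DMSO library, in DHPG 1 to 5. DHPG 6 stood 0.66 and 0.40 above the mean of the 3 deep DMSO libraries. The lncRNA and host transcripts had 0.13 (camera adjusted p = 0.033; adjusted p = 0.64 with an estimated correlation), with Gas5 at 0.57 ± 0.15, and of the 1560 annotated lncRNAs 0 passed.

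Ribosomal protein genes had a median of 0.31 with DHPG (camera adjusted p = 2.5e-13; adjusted p = 0.64 with an estimated correlation), for example Rpl3 at 0.41 and Rps12 at 0.47, but 0.02 with the library-set term. Of the lists of non-neuronal cells 3 had a camera call toward lower values, with medians of -0.58 for astrocytes (camera adjusted p = 0.00081; adjusted p = 0.64 with an estimated correlation), -0.69 for fibroblast, mural and meningeal cells (camera adjusted p = 0.0068; adjusted p = 0.64 with an estimated correlation) and -1.29 for choroid plexus and ependyma (camera adjusted p = 0.00059; adjusted p = 0.64 with an estimated correlation). With the library-set term these medians were -0.19, -0.22 and -0.34. Cycling cell markers had 0.41 (camera adjusted p = 0.0029; adjusted p = 0.64 with an estimated correlation) and 0.07 with the term. In mean log2 CPM, however, 5 of 6 DHPG libraries lay below every DMSO library of their own set for this list. The differences were -0.34 to 0.03, and for DHPG 1 to 5 that set holds DMSO 1 alone. Members of smallest p were Sox9 (-1.07) and Slc4a4 (-0.63), Igf2 (-2.41) and Vtn (-1.90), Foxj1 (-2.09) and Kl (-0.65), and Cdk1 (0.64) and Pcna (0.34).

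Lists without a camera call with DHPG had camera adjusted p of 0.72 for CREB/CRTC and cAMP-responsive genes (median -0.09, direction up), 0.57 for late-response genes, 0.71 for MAPK negative feedback, 0.11 for cAMP and PKA components, 0.27 for the group I mGluR pathway and 0.067 for glutamate receptors and postsynaptic density. They were 0.10 for mitochondrially encoded mRNAs, 0.67 for histones (median -0.02, direction up), 0.067 for heat shock, 0.11 for excitatory neurons, 0.72 for inhibitory neurons, 0.19 for microglia, 0.17 for the oligodendrocyte lineage and 0.067 for endothelium. Their members of smallest p were Rgs2 (0.50), Spry2 (0.43), Inhba (-1.14), Penk (0.72), Crebbp (-0.61), Ep300 (-0.99), Shank1 (-0.57), Ank2 (-0.47), mt-Nd2 (-1.45), mt-Nd4l (-1.48), Hist1h2bc (-0.48), Hist2h2bb (0.57), Hspe1 (0.36) and Dnajb1 (0.20). For cell types they were Nrgn (-0.89), Tbr1 (-0.64), Gad2 (-0.39), Dlx5 (-0.91), Aif1 (0.77), Tmem119 (-1.48), Cnp (-0.49), Sox10 (-0.62), Flt1 (-1.18) and Kdr (-1.07).

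**Figure D4:**
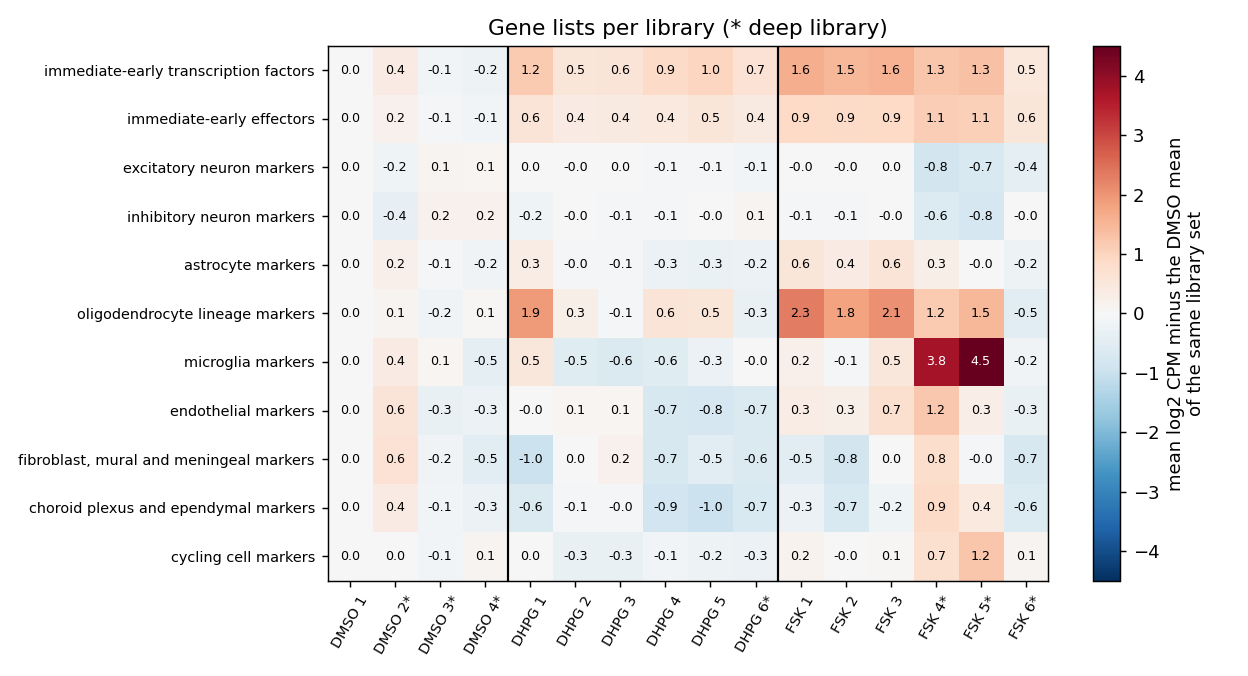
Mean log2 CPM of 11 gene lists (y axis) in each of the 16 total RNA libraries (x axis, asterisk for deep), minus the mean of the DMSO libraries of the same set (colour). Microglia markers reach 3.75 in FSK 4 and 4.47 in FSK 5.

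Of the genes fixed in advance, 7 were higher in FSK than in DHPG libraries. Npas4 was 1.68 ± 0.45 log2 units higher (39.4 CPM in DHPG, 126 in FSK; adjusted p = 0.019) and Fos 1.38 ± 0.37 higher (208 against 544 CPM; adjusted p = 0.019), each above every DHPG library in 6 of 6. Sik1 (0.96 ± 0.21, adjusted p = 0.016, 5 of 6), Nr4a1 (0.995 ± 0.33, adjusted p = 0.035, 3 of 6), Crem (0.45 ± 0.14, adjusted p = 0.029, 4 of 6), the postsynaptic scaffold gene Homer1 (0.49 ± 0.13, adjusted p = 0.021, 5 of 6) and Arl5b (0.50 ± 0.18, adjusted p = 0.045, 3 of 6) were higher too. Of these 7 genes Arl5b did not pass with the library-set term (0.35, adjusted p = 0.10). Arc (0.43 ± 0.26, adjusted p = 0.20), Egr1 (0.77 ± 0.43, adjusted p = 0.17), Per1 (0.31, adjusted p = 0.27), Bdnf (0.27, adjusted p = 0.16) and Grm5 (0.33, adjusted p = 0.097) did not pass.

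The 5 largest increases from DHPG to FSK, by the rule for named genes, were Steap4 (5.76 ± 1.34, adjusted p = 0.017), a metalloreductase, Mobp (5.75 ± 1.34, adjusted p = 0.017), a myelin protein, Fyb (5.46 ± 1.16, adjusted p = 0.016), an adaptor of blood cells, Lcn2 (5.22 ± 1.28, adjusted p = 0.017), a protein of reactive astrocytes, and complement C3 (5.10 ± 1.31, adjusted p = 0.018). They exceeded every DHPG library in 5, 3, 6, 5 and 3 of 6 FSK libraries. Without FSK 4 and FSK 5 and with the library-set term Steap4, Mobp, Lcn2 and C3 had 1.61, 1.54, 1.51 and 1.41 and did not pass, and Fyb was too low to be tested. Lower with FSK were Lsp1, a leukocyte actin-binding protein (-1.87 ± 0.43, adjusted p = 0.016, below every DHPG library in 6 of 6), Gm15501 (-3.67 ± 1.35, adjusted p = 0.049) and Gm48583 (-1.77 ± 0.55, adjusted p = 0.028). Gm49361 and Gm28900 had 0 counts in all 6 FSK libraries against 378 and 279 in DHPG, at least 182-fold and 134-fold lower (adjusted p = 0.024 and 0.035), from 4 and 3 of 6 DHPG libraries. In deep libraries alone Gm15501 had 0.44 and Gm48583 0.56.

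Between FSK and DHPG 2803 features were higher and 2480 lower with FSK, with a median size of 0.57 log2 units, and 7763 had unadjusted p under 0.05. Adjusted p was at lowest 0.0016, with 2 features under 0.01. With the library-set term 1959 were higher and 2048 lower, of which 3665 were shared. Without FSK 4 and FSK 5, 3 passed, and 1551 with the term added. Leaving out DHPG 2 (3031), DHPG 3 (1924), DHPG 5 (2380), FSK 4 (2575) or FSK 5 (1804) moved the count of 5283 by more than 1.5-fold. Of the lncRNAs 167 were higher and 54 lower.

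By list, 14 of 30 immediate-early transcription factors were higher and 1 lower in FSK than in DHPG (median 0.61, camera adjusted p = 7.9e-05; adjusted p = 0.66 with an estimated correlation). Of 31 effectors 13 were higher and 1 lower (median 0.49, camera adjusted p = 0.00011; adjusted p = 0.66 with an estimated correlation), and of 36 CREB/CRTC and cAMP-responsive genes 14 and 1 (median 0.30, camera adjusted p = 0.0040; adjusted p = 0.66 with an estimated correlation). Against no change, fry gave adjusted p of 0.046, 0.014 and 0.014. Ribosomal proteins had a median of -0.27 (7 lower; camera adjusted p = 3.6e-06), histones -0.56 (2 lower; 0.00035), mitochondrially encoded mRNAs 0.86 (5 higher; 0.015), microglia 2.56 (9 higher; 0.015) and the oligodendrocyte lineage 1.12 (6 higher, 1 lower; 0.022), each with adjusted p = 0.66 with an estimated correlation. With the library-set term 0 microglia markers passed.

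The remaining lists gave camera adjusted p in FSK against DHPG of 0.26 for late-response genes (3 higher, 3 lower), 0.11 for MAPK negative feedback (5 higher), 0.81 for cAMP and PKA components (4 higher, 6 lower), 0.81 for the group I mGluR pathway (6 higher, 9 lower) and 0.36 for glutamate receptors and postsynaptic density (2 higher, 6 lower). They were 0.23 for lncRNA and host transcripts (11 higher, 3 lower), 0.23 for heat shock (1 higher, 2 lower), 0.17 for excitatory neurons (3 lower), 0.23 for inhibitory neurons (2 higher, 3 lower), 0.056 for astrocytes (6 higher), 0.095 for endothelium (1 higher), 0.23 for fibroblast, mural and meningeal cells (0), 0.73 for cycling cells (0) and 0.19 for choroid plexus and ependyma (3 higher).

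The responses to FSK and DHPG across genes had a correlation of log2 fold changes of 0.18 (Spearman 0.02), and 0.48 (0.17) with the library-set term. Because both use the same 4 DMSO libraries, unchanged groups simulated against shared controls give 0.68 on average (0.65 to 0.70), or 0.63 with the term. The covariance was 0.052 against 0.134 simulated, and with the term 0.106 against 0.076 (0.069 to 0.085). The simulation drew each gene independently and so lacks variation that genes share between libraries. Its narrow ranges therefore cannot show whether 0.106 is an excess. With the controls split 2 and 2, so that each treatment had its own, the mean correlation was -0.0007 (-0.22 to 0.26), and 0.12 (0.046 to 0.22) with the term. The 100 genes higher with FSK of smallest p had a median log2 fold change with DHPG, against the other controls, of 0.37 with the term (0.18 to 0.56 over splits; 67 to 94 of 100 above 0) and 0.13 without it (-0.04 to 0.33). Trh was the 1 gene called higher with both, against the same 2 DMSO counts, and with the term it was not called with DHPG. For miRNA the correlation was -0.09, and 0.34 with the term (simulated 0.67 and 0.60).

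Mature miRNAs did not pass with FSK. MiR-132-3p and miR-212-3p, which CREB induces through their host transcript, had 0.07 ± 0.14 (95% interval -0.21 to 0.35, adjusted p = 0.86; 1691 CPM in DMSO and 1777 in FSK) and 0.13 ± 0.14 (-0.15 to 0.41, adjusted p = 0.79; 327 and 357 CPM). The neuronal miR-124-3p had -0.13 ± 0.16 (adjusted p = 0.80). Smallest p belonged to miR-666-3p (-0.50 ± 0.13, adjusted p = 0.32, below every DMSO library in 6 of 6), miR-770-5p (-0.66 ± 0.18, 6 of 6) and miR-410-5p (-0.96 ± 0.27, 5 of 6), all encoded in the imprinted Dlk1-Dio3 region. EdgeR called 0 of 556, with 53 at unadjusted p under 0.05, against 1 with DESeq2 and 30 with limma-voom, and without FSK 6 it called 5. The 33 Dlk1-Dio3 cluster miRNAs had a median of -0.17 (camera adjusted p = 0.0039; adjusted p = 0.70 with an estimated correlation). In mean log2 CPM this list differed from the DMSO mean by -0.50 and -0.47 in FSK 4 and FSK 5. In FSK 1, 2, 3 and 6 it differed by -0.04, 0.02, -0.03 and 0.14. Microglia and blood miRNAs (4 of 9 measured) had 1.29 with 2 higher over the list alone (camera adjusted p = 0.12), and their mean lay 1.89 and 2.40 above the DMSO mean in FSK 4 and FSK 5. Camera adjusted p was 0.59 for activity-regulated, 0.36 for neuron-enriched, 0.12 for oligodendrocyte lineage, 0.59 for endothelial, mural and fibroblast, 0.59 for muscle (1 measured) and 0.31 for let-7 miRNAs.

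With DHPG, miR-132-3p had 0.25 ± 0.14 (adjusted p = 0.43), miR-212-3p 0.14 ± 0.14 (adjusted p = 0.66) and miR-124-3p 0.06 ± 0.16 (adjusted p = 0.87). Smallest p belonged to miR-219a-5p, a miRNA of oligodendrocytes (-1.26 ± 0.39, adjusted p = 0.40, below every DMSO library in 5 of 6), miR-5100 (0.70 ± 0.22, above in 6 of 6) and miR-1982-3p (0.91 ± 0.29, 6 of 6). EdgeR called 0, with 61 at unadjusted p under 0.05, against 0 with DESeq2 and 175 with limma-voom, and without DMSO 1 it called 1. Dlk1-Dio3 miRNAs had a median of 0.13 (camera adjusted p = 0.034; adjusted p = 0.71 with an estimated correlation), and the other 7 lists had camera adjusted p of 0.56 to 0.78.

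Between FSK and DHPG 44 miRNAs were higher and 39 lower. Those of smallest p (adjusted p = 0.036 each) were miR-770-5p (-0.70 ± 0.16), miR-491-5p (-0.74 ± 0.17), miR-666-5p (-0.998 ± 0.24), miR-758-3p (-0.87 ± 0.21), miR-434-3p (-0.50 ± 0.12) and miR-672-5p (-0.67 ± 0.17), lower with FSK, and miR-24-2-5p (1.07 ± 0.25) and miR-219a-5p (1.48 ± 0.36), higher. MiR-24-2-5p exceeded every DHPG library in 6 of 6 and miR-219a-5p in 4 of 6, while miR-770-5p, miR-491-5p, miR-666-5p and miR-672-5p lay below in 6 of 6. MiR-132-3p (-0.17 ± 0.13), miR-212-3p (-0.01 ± 0.13) and miR-124-3p (-0.19 ± 0.14) did not pass. Of the Dlk1-Dio3 miRNAs 8 were lower, 10 over the list alone (median -0.30, camera adjusted p = 2.4e-05; adjusted p = 0.54 with an estimated correlation). Against the DMSO mean, the mean log2 CPM of this list stood at -0.50 and -0.47 in FSK 4 and FSK 5. It stood at -0.04 to 0.14 in FSK 1, 2, 3 and 6 and at 0.003 to 0.26 in DHPG libraries. The other lists had camera adjusted p of 0.91 for activity-regulated (3 higher, 2 lower; median -0.07, mean 0.05, direction down), 0.19 for neuron-enriched (2 lower), 0.19 for microglia and blood (3 higher), 0.098 for oligodendrocyte lineage (2 higher), 0.19 for endothelial, mural and fibroblast (2 higher), and 0.91 for muscle and for let-7. With the library-set term edgeR called 0 of the 83, with 143 at unadjusted p under 0.05 and 63 called by DESeq2. Leaving out DMSO 3 (54) or DMSO 4 (54), DHPG 2, DHPG 3, DHPG 4, DHPG 5, FSK 4 or FSK 5 (0 each), or DHPG 6 (128) moved the count by more than 1.5-fold.

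The authors' deposited table for FSK lists 1438 total RNA features at adjusted p under 0.05 (871 higher, 567 lower), which include all 139 found here. The authors' deposited table for DHPG lists 240 (41 higher, 199 lower). EdgeR called only 1 feature there, Trh, which is not among the 240. For miRNA the authors' deposited tables list 1 lower with FSK and 6 lower with DHPG.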

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

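The tests of the 3 patterns weighed here were chosen after the values had been seen. The comparison of each library with the others of its group was fixed before the data were examined.

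More genes passed between FSK and DHPG (5283) than between either treatment and DMSO. A difference shared by all libraries of a set is not the whole cause, because 69.4% of these genes also passed with the library-set term. FSK 4 and FSK 5 are both deep, so the term cannot exclude a difference confined to these libraries. In shallow libraries alone, where the groups are smaller, few genes passed (count given below). Whether FSK 4 and FSK 5 set apart from the other FSK libraries are the cause stays open: without them and with the term 1551 passed, while leaving out the other 14 pairs of FSK libraries gave 0 to 5182 with a median of 1364. Without the term, leaving out FSK 4 and FSK 5 gave 3, against a median of 2519 for the other pairs, and each pair that gave 2 or 3 contained FSK 4 or FSK 5. A true difference between the treatments stays open as well. The larger number of libraries (6 against 6) gave no gain on simulated counts. There edgeR recovered 13 of 67, 36 of 67 and 52 of 66 genes changed 1.5-, 2- and 4-fold for FSK against DHPG. For FSK against DMSO it recovered 13 of 67, 38 of 67 and 55 of 66. These values argue against the number of libraries as the cause, though variation that genes share between libraries was not simulated.

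Microglia markers stood higher with FSK, with a median log2 fold change of 2.98. Cells of other types in FSK 4 and FSK 5 could account for most of it: without these libraries and with the library-set term the median was 0.00065, and it was 0.84 without the term. The microglial genes C1qa and C1qc had 34.7 and 26.0 CPM in FSK 4 and 54.6 and 46.3 CPM in FSK 5, against 0.6252 to 7.67 and 0.425 to 4.66 in all other libraries. A difference shared by all libraries of a set does not account for the 2.98, as the median was 2.93 with the term. FSK 4 and FSK 5 are both deep, so the term cannot exclude a technical difference confined to these libraries. Forskolin raising the markers by this much in every culture is excluded: against the DMSO libraries of their own set, which for FSK 1 to 3 is DMSO 1 alone, the mean log2 CPM of the list differed by 0.24, -0.07, 0.51 and -0.16 in FSK 1, 2, 3 and 6 and by 3.75 and 4.47 in FSK 4 and FSK 5 (median of the 6, 0.375).

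The host transcript of miR-212 and miR-132 rose with FSK while the mature miRNAs did not pass. Too few miRNA counts are excluded for a large change, because the higher upper end of the 95% intervals was a log2 fold change of 0.41. A difference between library sets is excluded for the host, whose smaller log2 fold change within 1 set was 3.51. A delay between transcription and mature miRNA at 30 minutes stays open, as no later time was analysed here.

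Each named gene and list was also looked at library by library within its group. Of 474 such tests 56 stood apart, where 23.7 are expected by chance. DHPG 6 accounts for 20 and DMSO 1 for 17, and each is the lone library of its set in its group.

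DHPG 6, the only deep DHPG library, held 42656784 counts (42.7 in units of 1e6) with 11.4% mitochondrial rRNA. It was the highest DHPG library in CPM for C3 (30.4), Crebbp (85.2), Dlx5 (1.55), Egr1 (141), Ep300 (41.5), Fgfr3 (142), Foxj1 (57.2), Igf2 (33.3), Lmtk3 (115), mt-Nd2 (319), Nrgn (104) and Per1 (41.5), and the lowest for Cdk1 (6.84). In mean log2 CPM it was highest for immediate-early effectors (4.75), MAPK negative feedback (4.77), excitatory neuron markers (5.08) and endothelial, mural and fibroblast miRNAs (4.81), and lowest for cycling cell markers (2.62).

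DMSO 1, the only shallow DMSO library, was the highest DMSO library in CPM for Aif1 (3.27), Cx3cr1 (1.90), Gm15501 (29.9975), Gm28900 (6.19), Gm48583 (11.1), Gm49361 (3.53), Hist2h2bb (52.7), Lsp1 (11.6), Pcna (43.5), Spry2 (81.7), miR-666-5p (2055) and miR-758-3p (496). It was the lowest for Ep300 (15.9), Pde7a (16.2) and Sox10 (4.95), and in mean log2 CPM for CREB/CRTC and cAMP-responsive genes (4.36) and the oligodendrocyte lineage (3.44).

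FSK 5 was the highest FSK library in CPM for Egr2 (26.9), Fyb (13.5), Lcn2 (549), mt-Cytb (1370) and Steap4 (134). FSK 4 was highest for Slco1a4 (83.8) and Tmem119 (6.79) and lowest for Npas4 (97.8). FSK 6 was highest for Gad2 (113) and lowest in mean log2 CPM for histones (2.37), and FSK 1 highest for Inhba (2.53 CPM). Among DHPG libraries, DHPG 1 was highest for Aqp4 (207) and Ctss (2.15), DHPG 4 lowest for Dnajb1 (36.5) and DHPG 3 stood apart for miR-5100 (33.8). Among DMSO libraries, DMSO 2 stood apart for AW047730 (19.5), Fosb (11.3) and Kdr (22.6), and DMSO 4 for Grm5 (256).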

How the results depend on the processing

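Fits with a library-set term, within 1 library set, or without FSK 4 and FSK 5 were chosen after the values had been seen. The others were fixed beforehand. The cause of the changes given here was not tested.

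For FSK against DMSO in total RNA (139 called) library totals only gave 62 (49 higher, 13 lower, against 60 and 79), the DESeq2 Wald test 1234, limma-voom with sample quality weights 6033, no filter on low counts 66, the libraries of the 2 groups alone 83, 1 surrogate variable (svaseq) 1433 and a minimum fold of 1.2 18. DESeq2 size factors gave 146 and the filter of 50 counts 164. Leaving out 1 library gave 12 (without DMSO 3) to 427 (without DHPG 6). The library-set term gave 1622, the term with DESeq2 3295, deep libraries only 151 and shallow libraries only 11. FSK 4 and FSK 5 left out gave 38, and 56 with the library-set term.

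For DHPG against DMSO in total RNA (1 called) the DESeq2 Wald test gave 9, limma-voom with sample quality weights 5940 and 1 surrogate variable (svaseq) 3. At least 50 counts in 4 or more libraries gave 0, and so did the libraries of the 2 groups alone (0). With 1 library left out edgeR called 0 (without DMSO 3, and without DMSO 4) to 5 (without DMSO 2). The library-set term gave 0, deep libraries only 0, shallow libraries only 0, FSK 4 and FSK 5 left out 0 and the same with the library-set term 0. These are edgeR counts, with 400, 465, 387 and 3425 features at unadjusted p under 0.05 for the first 4, and DESeq2 with the library-set term gave 39. On simulated data of this design, with genes drawn independently, limma-voom made 1624 false calls among 1762, DESeq2 103 among 223 and edgeR 10 among 105. The larger counts of the first 2 therefore carry less weight, though variation that genes share between libraries was not simulated.

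For FSK against DHPG in total RNA (5283 called) library totals only gave 2510 (1760 higher, 750 lower, against 2803 and 2480), no filter on low counts 2905, 1 surrogate variable (svaseq) 1913 and a minimum fold of 1.2 4. Leaving out 1 library gave 1804 (without FSK 5) to 5798 (without FSK 3). Deep libraries only gave 0 with edgeR, with 4587 at unadjusted p under 0.05, where DESeq2 on all libraries gave 6422 and limma-voom 5764. Shallow libraries only gave 9, FSK 4 and FSK 5 left out 3, and 1551 with the library-set term.

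For miRNA, FSK against DMSO (0 called by edgeR, 53 at unadjusted p under 0.05), the DESeq2 Wald test gave 1, limma-voom with sample quality weights 30 and 1 surrogate variable (svaseq) 2. Leaving out 1 library gave 0 (for example without DMSO 1) to 5 (without FSK 6), and DESeq2 with the library-set term 14. For miRNA, DHPG against DMSO (0 called by edgeR, 61 at unadjusted p under 0.05), limma-voom with sample quality weights gave 175 and DESeq2 0. Leaving out 1 library gave 0 (for example without DMSO 2) to 1 (without DMSO 1).

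For miRNA, FSK against DHPG (83 called), no filter on low counts gave 35, 1 surrogate variable (svaseq) 0 and a minimum fold of 1.2 0. With 1 library removed the count was 0 (without DHPG 2, among others) to 128 (without DHPG 6). The library-set term gave 0, deep libraries only 0, shallow libraries only 0, FSK 4 and FSK 5 left out 0 and the same with the library-set term 0. These are edgeR counts, and the sets are those of the total RNA libraries, not depth groups of the miRNA libraries. With the term 143 had unadjusted p under 0.05 and the lowest adjusted p was 0.069, and without it DESeq2 gave 107 and limma-voom 102.

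A replicate block treats libraries with the same number as paired. Numbers were not taken as pairs, as only 3 of 14 pairs in each assay correlated above 0.1 in their residuals. These were DMSO 1 with FSK 1, DHPG 3 with FSK 3 and DHPG 6 with FSK 6, each within 1 library set. Their correlations were 0.39, 0.16 and 0.22 in total RNA and 0.41, 0.19 and 0.17 in miRNA. DMSO 1 with DHPG 1, also within 1 set, had -0.18 and -0.39. The lowest, DMSO 2 with FSK 2 (-0.41 and -0.45), joins a deep and a shallow library. A pairing is therefore not ruled out. With the replicate block edgeR called 531 in total RNA for FSK against DMSO (112 shared with the 139), 0 for DHPG against DMSO and, in miRNA, 0 for FSK against DHPG. The library-set term and replicate block together gave 4598 for FSK against DMSO, 0 for DHPG against DMSO and 1882 for FSK against DHPG in total RNA, and 69 for FSK against DMSO and 0 for FSK against DHPG in miRNA. Gene lists of miRNA with the replicate block gave 0 camera calls for FSK against DMSO and 0 for DHPG against DMSO.

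Gene lists in total RNA depended on the correlation assumed. For FSK against DMSO (9 lists with a camera call) an estimated correlation gave 0, fry 5, the library-set term 14, and the term with an estimated correlation 1. For DHPG against DMSO (8 lists) an estimated correlation gave 0, fry 0 and the library-set term with an estimated correlation 2. For FSK against DHPG (8 lists) an estimated correlation gave 0, fry 3 and the library-set term with an estimated correlation 0. Directions reversed with the library-set term for ribosomal proteins with FSK (adjusted p = 0.031) and, with DHPG, for MAPK negative feedback (adjusted p = 0.0012, or 0.022 with an estimated correlation) and replication-dependent histones (adjusted p = 1.8e-06).

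Over all lists of both assays 75 results kept their direction and side of the limit with the library-set term, 9 gained a call, 3 lost it and 3 reversed.

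Gene lists in miRNA gave 1 camera call in each comparison. For FSK against DMSO an estimated correlation gave 0, the library-set term with an estimated correlation 0 and fry 0. For DHPG against DMSO an estimated correlation gave 0, the library-set term 0, the term with an estimated correlation 0 and fry 0. For FSK against DHPG an estimated correlation gave 0 and the library-set term with an estimated correlation 0.

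Among named genes signs reversed for Slco1a4 with FSK against DMSO under limma-voom with sample quality weights (-1.37), and for Gm15501 (0.44) and Gm48583 (0.56) between FSK and DHPG in deep libraries only.

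The correlation of the responses to FSK and DHPG in total RNA (0.18) was -0.00067 with controls split 2 and 2 (mean of 6), 0.0099 at an average log2 CPM of at least 3, 0.48 with the library-set term, 0.63 with FSK 4 and FSK 5 left out and 0.50 with both. For miRNA (-0.09) these values were -0.20, -0.16, 0.34, 0.53 and 0.29.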

Other observations

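The Mantel test and the test on all 15 snoRNA host genes were chosen after the values had been seen. The rearrangements of group labels, the test of the other snoRNA host genes and the test of gene span were set down before they were run.

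Rearranged labels show whether chance can be excluded as the source of a count. For FSK against DMSO 3 of 100 arrangements, the real one included, called at least 139 features, and the highest other called 2615. That arrangement groups DMSO 1 and DMSO 3 with FSK 1, 2, 3 and 6 and so parts FSK 4 and FSK 5 from most others, which points to structure of the samples. Within library sets 1 of 80, the real one, reached 1622, which is the smallest share this test can give, so chance is unlikely there. The next, with 768, exchanged DMSO 2 and FSK 6 and kept FSK 4 and FSK 5 together. These counts therefore do not tell treatment from a difference confined to FSK 4 and FSK 5. For FSK against DHPG 1 of 100 reached 5283 (next 4244), and within sets 1 of 100 reached 4007 (next 1). The arrangement with 4244 exchanged only DHPG 1 and FSK 3, which points to structure of the samples here too. On the second principal component of total RNA DHPG 1 (28.5) lay among FSK 1 to 3 (25.3 to 34.2), above the other shallow DHPG libraries (-16.1 to 20.7).

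For DHPG against DMSO 5 of 100 arrangements called at least 1 feature (highest other 884), so chance is not excluded for that count, and the highest points to structure of the samples. For miRNA between FSK and DHPG 1 of 100 free arrangements, the real one, reached 83 (next 67). These ignore library set, in which the groups differ (1 deep DHPG library, 3 deep FSK libraries). They therefore cannot tell treatment from library set, and within sets the real count was 0. Where the real edgeR count is 0, each arrangement reaches it by construction and the comparison says nothing about chance. That holds for DHPG against DMSO in total RNA within sets (24 of 24, highest other 6) and for miRNA in FSK against DMSO (100 of 100, highest other 103; within sets 80 of 80, highest other 35). It also holds for miRNA in DHPG against DMSO (100 of 100, highest other 55; within sets 24 of 24, highest other 11) and, within sets, in FSK against DHPG (100 of 100, highest other 1).

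The snoRNA host genes Gas5, Snhg1 and Snhg15 (1.21 ± 0.25, adjusted p = 0.036) rose with FSK, which raises the question of a response of all such hosts. The 12 other measured Snhg genes had a median log2 fold change of 0.04, at percentile 41.6 of random sets of like expression (-0.17 to 0.35). Among them Snhg14 had 0.65 (adjusted p = 0.078; 0.038 with the library-set term). All 15 hosts, the 3 called ones included, had a median of 0.14 at percentile 78 (-0.17 to 0.30), so a rise of the class as a whole was not seen. With DHPG the 12 had a median of 0.29 at percentile 99.8, and 88.7 with the library-set term.

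Genes changed by FSK were compared with others in genomic span. The 52 raised genes with a known position had a median span of 7.96 kb, against 15.8 to 38.5 kb for random sets of like expression, and 77 lowered genes 11.985 kb against 19.1 to 38.4 kb. A short gene can be transcribed in full within 30 minutes, which could favour raised short genes, yet with the library-set term the raised genes had 24.97 kb against 18.3 to 24.1 kb. Whether raised genes are short therefore depends on the fit and stays open, while the lowered genes stayed short with the term (11.95 kb against 27.1 to 32.5 kb). The spans were compared only with FSK 4 and FSK 5 included. Without these libraries and with the term 11 features were lower. A difference confined to FSK 4 and FSK 5 is therefore not excluded for the lowered genes. The cause of their short spans was not tested, and a time course with measured mRNA half-lives would address turnover only.

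Cultures of shared origin would share their ratio of Xist to Y-linked transcripts, so pairs of libraries close in that ratio would also be close over the other genes. Over the 57 pairs within a library set, differences in the ratio and distances in total RNA over genes outside the sex chromosomes had a correlation of 0.15 (Mantel p = 0.142), and 0.45 without FSK 4 and FSK 5, which leaves the question open.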
